A study of Mus musculus with 6 samples.

How the data were processed

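The samples were whole aortas of 6 mice, 3 with floxed Dicer and lysozyme M-driven Cre (Dicer_KO) and 3 littermates with wild-type Dicer and the same Cre (Dicer_WT), all Apoe-deficient. Per the labels, total RNA was isolated after perfusion of the vessels, reverse-transcribed with a TaqMan microRNA kit, preamplified and read with FAM-labelled probes. The labels give aorta as the tissue and macrophage as the cell type, and the values were read here as those of whole aortas. The labels call the replicates biological, so each aorta was taken as 1 animal. The software and threshold behind the Ct values, the array version and lots, and any date of measurement are not given in the sources used here, so no technical batch was testable.

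A table deposited by the authors holds Ct per assay and aorta, with 40 for wells without product, and repeats 6 control RNAs in blocks that form 2 cards of 335 and 182 microRNA assays. In it, 5 cells had a decimal comma, which was read as a point. A further table deposited by the authors holds relative quantities, a linear ratio per assay and aorta. From the values, log2 of this ratio deposited by the authors equals the mean Ct of reference RNAs of the same aorta and card minus the assay's Ct, scaled so that the geometric mean of the Dicer_WT aortas is 1. The references were U6, snoRNA135 and snoRNA202 on the first card (largest difference 2.41e-10), joined by snoRNA429 on the second (3.28e-10). U87 and Y1 were not among them, and wells at Ct 40 were carried through as measured. The third table, the authors' deposited fold changes, holds Dicer_KO over Dicer_WT as a linear ratio.

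These choices were fixed before the data were examined. An assay was detected below Ct 35. Undetected wells were set to Ct 35 and brought to the relative scale by the offset of their aorta and card, so a fold against a silent group is a bound. Assays detected in at least 2 of 3 aortas of at least 1 group were tested, 377 of 517, without control RNAs and the plant control assay. Log2 values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all assays tested, threshold 0.05). Single quantities per aorta were compared by exact permutation tests, whose smallest two-sided p is 0.1. Of 17 lists of microRNAs fixed in advance, 16 had at least 3 assays tested and were compared with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists, beside camera with an estimated correlation and fry. List members were matched by assay name, ignoring a final arm label where the array held 1 assay of that number. Members listed without an arm were not matched where the array held both arms, nor to an assay with a further letter. Among those left out were assays of miR-129 and miR-128 in the neuronal list, of miR-128 in the lipid metabolism list and of miR-540 and miR-673 in the Dlk1-Dio3 list. Several members stand in more than 1 list, and the cell types named are those in which a microRNA is abundant, not exclusive.

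The assays named were all calls, filled up in each direction to 10 by unadjusted p, the members of the myeloid, smooth muscle, endothelial, blood and let-7 lists as examples, miR-10a, let-7b and miR-195, assays detected in every aorta of 1 group and none of the other, and the control RNAs. Assays named outside this rule were chosen after their values were seen: miR-467a, miR-467b, miR-467c, miR-467e, miR-183, miR-96, miR-501-5p, miR-150, miR-122, miR-193b, miR-219, miR-127, miR-337-3p and miR-543. So were miR-181c and miR-31 of the lymphoid list, and miR-128a, miR-129-5p, miR-453, miR-540-5p, miR-673-3p and miR-673-5p, which stand outside the lists as matched. The assays of this last sentence are not in the counts of alternatives for named assays.

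The steps were tested on 20 simulated tables of 517 assays, 3 aortas against 3. Of assays lowered by 0.5 on the log2 scale 10.3% were called, of those lowered by 1 64.3%, by 2 90.7% and by 3 97.0%, and 5.52% of calls fell on unchanged assays. A list shifted by 1 was called in 100% of tables, and with nothing shifted the median count of calls was 0. The noise was drawn independently for each assay, so list members were uncorrelated in the simulations. In the data the estimated correlation of members was 0.57 for the myeloid and 0.47 for the Dlk1-Dio3 list. The simulations therefore do not test list calls under such correlation. The shares of lowered assays called hold for the simulated noise and may be too high for the data. In the data miR-511 at -1.99, miR-342-5p at -1.83 and miR-223 at -1.66 were not called, whereas miR-467d at -2.67 and miR-431 at -2.26 were. The count of calls was 7 over all assays tested and 22 over assays detected in all 6 aortas, with miR-511, miR-342-5p and miR-223 among the latter.

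Alternatives fixed in advance were non-normalized Ct, centring on the mean, other reference RNAs, quantile normalization, Ct cutoffs of 32 and 38, missing in place of set values, stricter or no filtering, a trended and robust variance, the replicate number as a block and leaving out each aorta. Wells at Ct 40 taken as measured, U87 and Y1 as the reference the snoRNA assays as the reference and the Dlk1-Dio3 list joined by 5 other assays of the locus, passenger strands left out, were chosen after seeing the data. No aorta repeated the Ct values of another. The reference annotation supplied (GRCm38.p6) was used only to find which microRNA genes lie among those of the Dlk1-Dio3 list, and no positions are given, because the arrays name no genome build. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.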

Results

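MicroRNA levels were measured in whole aortas of 6 male Apoe-deficient mice, which develop atherosclerosis on a fat-rich diet. In 3 mice, Cre recombinase from the lysozyme M locus met 2 floxed copies of Dicer, the endonuclease that cuts most microRNA precursors (Dicer_KO aortas). The other 3 mice were littermates with the same Cre and wild-type Dicer (Dicer_WT aortas). Lysozyme M is active in macrophages, monocytes and neutrophils, and in which cells of the vessel wall Dicer was lost was not measured. Feeding began at 6 to 8 weeks of age and lasted 12 weeks, with 21% crude fat. Each aorta was read once per microRNA by TaqMan PCR on 2 array cards with 517 microRNA assays, as a threshold cycle (Ct), in which 1 cycle less means about 2 times the RNA. Each aorta was taken as that of 1 mouse, since the labels call the replicates biological, and the number of arrays limits the precision. Dicer mRNA was not measured on these arrays, so the labels of the genotypes had no check in the data.

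Below Ct 35, taken as detected, lay 374, 378 and 374 assays in the Dicer_WT aortas and 366, 357 and 349 in the Dicer_KO aortas. The means were 375.3 ± 2.31 and 357.3 ± 8.50 (SD, n = 3 each), a difference of -18 assays (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). Over all aortas, 330 assays were detected in all 6 and 113 in none. The negative control assay for a plant microRNA gave no product in any aorta.

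The comparison asked which microRNAs of the atherosclerotic aorta depend on Dicer in lysozyme M-expressing cells. In Dicer_KO aortas, 7 microRNA assays were called lower and 0 higher (limma, adjusted p under 0.05 among 377 assays tested). Of these 7, 5 gave no product in any Dicer_KO aorta: miR-501-3p, miR-504, miR-881*, miR-665 and miR-761. For these 5, an array lot that differed between genotypes cannot be told apart from the genotype, as no lot is recorded. The other 2 were miR-467d, from a mouse family of repeated microRNA genes, and miR-431, which like miR-665 comes from the imprinted Dlk1-Dio3 locus. Among 11 assays of macrophage-enriched and other myeloid microRNAs, 8 lay lower in every Dicer_KO aorta than in every Dicer_WT aorta. These 8 included miR-223 and miR-511, but 0 of the 11 passed the threshold over all assays. Over alternative settings, miR-511 passed in 8 of 21 and miR-223 and miR-342-3p in 5 of 21 each. miR-147 passed in 3 of 19, miR-342-5p in 1 of 21 and the other members in none. At an unadjusted p under 0.05, 92 assays were lower and 9 higher.

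The lowest log2 fold change of the 377 assays was that of miR-501-3p, with a Ct of 25.1 ± 0.507 in Dicer_WT aortas (SD, n = 3) and 40 in every Dicer_KO aorta. It was at least 802-fold lower, with the silent wells set to Ct 35 (limma adjusted p = 9.04e-06). By the same bound, miR-504 was at least 165-fold lower (adjusted p = 3.38e-05) and miR-881* at least 27.1-fold lower (adjusted p = 7.28e-04). For miR-665 the bound was 19.8-fold (adjusted p = 8.77e-05) and for miR-761 it was 9.22-fold (adjusted p = 7.28e-04), a call lost at a Ct cutoff of 32 (log2 fold change -0.21, adjusted p = 0.513, the largest over its alternatives). At a Ct cutoff of 32 the others stayed called, with smaller bounds. Their log2 fold changes were then -6.65 for miR-501-3p, -4.36 for miR-504, -1.76 for miR-881* and -1.31 for miR-665. The adjusted p-values at Ct 35 treat the silent wells as measured there, which leaves out the true spread. The other arm of the miR-501 hairpin, miR-501-5p, was detected in 2 of 3 Dicer_KO aortas, with a log2 fold change of -3.38 ± 1.44 (SE, n = 3 each, limma adjusted p = 0.199). This value rested on the silent well, since it was -1.65 without Dicer_KO replicate 3 and -4.33 without Dicer_KO replicate 1, and the assay was chosen for it after the data had been seen. With undetected wells left missing, miR-501-5p was called lower, at -1.65 (adjusted p = 0.0460, from 0.0460 to 0.397 over its alternatives). miR-467d fell by 2.67 ± 0.302 on the log2 scale (SE, adjusted p = 0.0083) and miR-431 by 2.26 ± 0.353 (adjusted p = 0.0400), each lower in 3 of 3 Dicer_KO aortas than in every Dicer_WT aorta. The call of miR-467d was lost after quantile normalization (-1.75, adjusted p = 0.103, from 0.00212 to 0.103 over its alternatives), and that of miR-431 relative to U6 alone (-2.43, adjusted p = 0.0549), with no filter on detection (adjusted p = 0.0577) and with wells at Ct 40 taken as measured (adjusted p = 0.0526), from 0.00842 to 0.178 over its alternatives. In total, 7 assays were detected in all Dicer_WT and no Dicer_KO aortas, against 0 the other way round. The remaining members of this set were miR-147, at least 12.8-fold lower (adjusted p = 0.0691), and miR-488, at least 2.5-fold lower (adjusted p = 0.298), neither of which passed the threshold. The value of miR-488 rested on Dicer_WT replicate 3, without which the log2 fold change was -0.35 against -1.32, and that of miR-147 was -2.84 without Dicer_WT replicate 1 against -3.67.

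**Figure D1:**
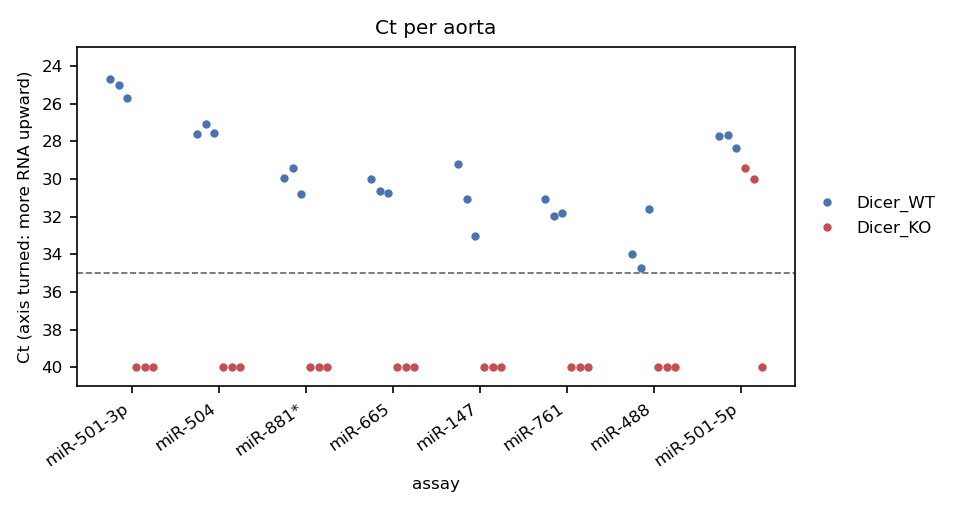
Ct per aorta (vertical axis, turned so that more RNA lies higher) for the 7 assays detected in every Dicer_WT aorta (blue) and in no Dicer_KO aorta (red), and for miR-501-5p, with the cutoff of Ct 35 as a dashed line. Every Dicer_KO well of the 7 assays lies at Ct 40, whereas miR-501-5p was silent in 1 Dicer_KO aorta.

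After these and the myeloid miR-511, the smallest unadjusted p-values below 0 were those of miR-330* (log2 fold change -1.09 ± 0.194, limma adjusted p = 0.0542) and miR-301b (-1.22 ± 0.219, adjusted p = 0.0542). The highest-ranked values above 0 were those of miR-182 at 1.70 ± 0.327 (SE, limma adjusted p = 0.0626) and miR-129-3p at 1.11 ± 0.248 (adjusted p = 0.0691). These non-calls depended on the setting. Over 21 alternatives, miR-330* passed as lower in 7 and miR-301b in 6, and miR-182 passed as higher in 7 and miR-129-3p in 8. The further 8 assays ranked above 0 had adjusted p-values of 0.148 to 0.190 and were miR-200b* at 3.56 (detected in 1 of 3 Dicer_WT aortas), miR-378* at 1.09, miR-802 at 2.44, miR-451 at 1.36, miR-33* at 0.54, miR-193* at 0.48, miR-216b at 2.71 (1.57 without Dicer_WT replicate 2) and miR-378 at 0.91. The value of miR-200b* followed the level set for the silent wells, from 0.72 with these left missing to 6.90 with Ct 40 taken as measured, and the assay was called higher without Dicer_WT replicate 2 (4.98, adjusted p = 0.00762, from 0.00762 to 0.445 over its alternatives). The microRNAs miR-10a, let-7b and miR-195, named in advance, had log2 fold changes of -0.52 ± 0.260, -0.64 ± 0.294 and -0.32 ± 0.190 (SE, limma adjusted p = 0.226, 0.225 and 0.274), none past the threshold. miR-10a was at -0.32 without Dicer_KO replicate 3, and miR-195 turned to 0.042 with mean centring and to 0.19 relative to the control RNAs U87 and Y1.

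Of 11 myeloid assays tested, 0 passed over all assays, 6 were lower when adjusted over the list alone, and all 11 had a log2 fold change below 0 on the authors' scale, of which miR-132, miR-142-3p and miR-142-5p turned above 0 relative to U87 and Y1. The 6 were miR-511, miR-223, miR-342-3p, miR-147, miR-342-5p and miR-146a. miR-223, a granulocyte and macrophage microRNA, had a log2 fold change of -1.66 ± 0.346 (SE, limma adjusted p = 0.0641 over all assays). miR-511, which lies in the gene of the macrophage mannose receptor, had -1.99 ± 0.340 (adjusted p = 0.0542), and miR-146a, a brake on inflammatory signalling, -0.93 ± 0.271 (adjusted p = 0.106). The pan-leukocyte miR-142-3p and miR-142-5p had the values nearest to 0, at -0.07 and -0.09, with a 95% interval of -0.63 to 0.48 for the former, and both turned above 0 with mean centring or quantile normalization too. The list's median was -0.93 and camera's adjusted p was 0.0757 (adjusted p = 0.946 with an estimated correlation). That adjusted p passed the threshold in 6 of 23 alternatives. The erythroid microRNAs miR-451, which matures without Dicer, and miR-486 had log2 fold changes of 1.36 and 1.12, and 0 of these 2 passed, adjusted over the list alone or over all assays. Without Dicer_WT replicate 3 they were at 0.80 and 0.68.

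Among 34 assays of the Dlk1-Dio3 list, fixed in advance from this imprinted cluster, 33 had a log2 fold change below 0, 1 fell over all assays (miR-431) and 12 were lower when adjusted over the list alone. The median was -0.82 and the list stood lower than the other assays (camera adjusted p = 0.00121), a call lost with an estimated correlation (adjusted p = 0.946). The list as matched left out the passenger strands of its hairpins, miR-665, which fell too, and 4 further assays whose genes lie among its own. These 4 were miR-453, miR-540-5p, miR-673-3p and miR-673-5p. The list names miR-540 and miR-673 without an arm, and such names were not matched where the array held both arms. With miR-665 and these 4, but without passenger strands, joined after the data had been seen, 38 of 39 assays were below 0, 2 fell over all assays (miR-431 and miR-665) and the median was -0.84 (camera adjusted p = 1.68e-04, and adjusted p = 0.946 with an estimated correlation). Examples chosen after their values were seen were miR-543 at -1.11 ± 0.220 (SE, limma adjusted p = 0.0641), miR-337-3p at -1.06 ± 0.202 (adjusted p = 0.0626) and the abundant miR-127 at -0.63 ± 0.180 (adjusted p = 0.101).

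Of 7 smooth muscle assays, 0 passed, over all assays or adjusted over the list alone, with a median of -0.43, which turned to 0.080 relative to U87 and Y1. The contractile-phenotype pair miR-143 and miR-145 had log2 fold changes of -0.76 ± 0.255 and -0.42 ± 0.215 (SE, limma adjusted p = 0.137 and 0.231). Of 6 endothelial assays 0 passed, over all assays or adjusted over the list alone, and the median was -0.23, which turned above 0 with mean centring and quantile normalization and to 0.28 relative to U87 and Y1. It was -0.43 without Dicer_KO replicate 2 and -0.13 without Dicer_KO replicate 3. The angiogenic miR-126-3p was at -0.01, with the same turns, and miR-221 at -0.98 ± 0.272 (adjusted p = 0.101). All 8 let-7 assays were below 0 with a median of -0.62, and 0 passed, over all assays or adjusted over the list alone (camera adjusted p = 0.323). In this family let-7a was at -0.74 and let-7e at -0.76, and let-7f and let-7g turned above 0 relative to U87 and Y1, as did let-7f after quantile normalization.

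The epithelial list of 10 assays stood higher than the other assays (camera adjusted p = 0.0460), with a mean of 0.33 but a median of -0.13. The call was lost with an estimated correlation (adjusted p = 0.946). Its highest members were miR-96 (detected in 2 of 3 Dicer_WT aortas) and miR-182, at 2.49 and 1.70, of which miR-182 passed adjusted over the list alone and 0 passed over all assays. The liver and adipose list of 6 assays stood higher too (camera adjusted p = 0.0460, median 0.27; adjusted p = 0.946 with an estimated correlation), with the hepatocyte microRNA miR-122 at 1.36 ± 0.687 (SE, limma adjusted p = 0.228) and 0 members past the threshold, over all assays or adjusted over the list alone. Without Dicer_WT replicate 3, miR-122 was at 0.64 and the median of this list at 0.084. Of the remaining lists 0 passed in camera. Their medians were -0.26 for lymphoid (4 assays), -0.07 for striated muscle (5 assays), -0.21 for neuronal (6 assays), -0.47 for the miR-10, miR-99 and miR-125 families (7 assays), -0.32 for the miR-15, miR-16 and miR-195 family (6 assays), -0.24 for the miR-17-92 clusters (11 assays), -0.25 for the miR-29 and miR-30 families (8 assays), -0.44 for lipid metabolism (10 assays) and -0.37 for passenger strands (86 assays). Leaving out 1 aorta moved several of these medians by over 1.5 times: lymphoid from -0.46 to -0.14, striated muscle from -0.35 to 0.17, neuronal from -0.72 to 0.38, the miR-10 families from -0.67 to -0.094, the miR-17-92 clusters from -0.39 to -0.16 and the miR-29 and miR-30 families from -0.30 to -0.14. The extremes came without Dicer_KO replicates 1 and 2 for lymphoid, 3 and 2 for striated muscle, 2 and 3 for neuronal and 1 and 3 for the miR-10 families, and without Dicer_WT replicate 3 and Dicer_KO replicate 3 for the others. Adjusted over the list alone, miR-219 passed in the neuronal list, miR-223 in the lipid list and miR-881* in the passenger list. The neuronal list names miR-129 and miR-128, but name matching left out miR-129-3p, miR-129-5p and miR-128a. Of these, miR-129-3p and miR-129-5p lay higher on average in Dicer_KO aortas and miR-128a lower. The lipid metabolism list names miR-128 too, and miR-128a was left out there as well. The neuronal and lipid metabolism medians with these assays were not computed. Relative to U87 and Y1, the medians of the myeloid (-0.42), Dlk1-Dio3 (-0.31) and let-7 (-0.11) lists stayed below 0 and those of all other lists lay above it. fry called 0 of the 16 lists tested.

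**Figure D2:**
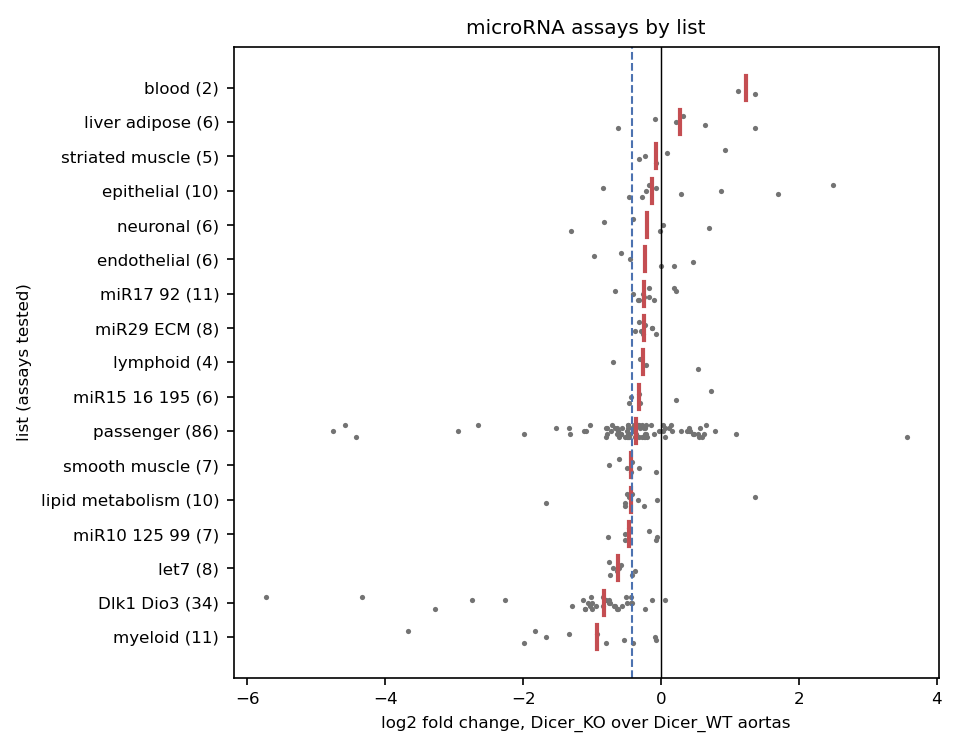
Log2 fold change of each assay tested (grey points, horizontal axis, Dicer_KO over Dicer_WT), by list (vertical axis, with the number of assays), with the list median in red. The dashed line marks the median of all 377 assays, -0.42, and the myeloid and Dlk1-Dio3 medians of -0.93 and -0.82 lie furthest below it.

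On the authors' scale the distribution was shifted below 0, though not for every assay. Of 377 assays, 295 (78.2%) had a log2 fold change below 0 and the median was -0.42, a fold of 0.749. Per aorta, the median deviation from the Dicer_WT mean was 0.003 ± 0.15 in Dicer_WT and -0.41 ± 0.206 in Dicer_KO aortas (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The groups did not overlap for 132 of 377 assays (123 lower in Dicer_KO and 9 higher), where chance gives 10% of assays. The assays share the same aortas and are not independent. A shift common to them can part many at once, so this share is no evidence beyond the permutation test of the median. The size and sign of this shift followed the reference RNA, with -0.61 relative to U6 alone and 0.16 relative to U87 and Y1, against -0.64 without normalization. Mean centring and quantile normalization, which use no reference RNA and bring the centres of the aortas together by construction, gave -0.13 and -0.010. With U87 and Y1 as the reference, or after quantile normalization, 7 assays were called lower and 2 higher.

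Control RNAs, which are made without Dicer, had unequal differences. On the authors' scale, as a mean of both cards, U87 differed by -0.44 between Dicer_KO and Dicer_WT aortas (exact permutation p = 0.1, 3 of 3 Dicer_KO aortas below every Dicer_WT aorta) and Y1 by -0.71 (exact permutation p = 0.2). The reference RNAs differed by 0.21 for U6, -0.13 for snoRNA135, -0.04 for snoRNA202 and -0.07 for snoRNA429 (exact permutation p = 0.4, 0.4, 0.7 and 0.4). Single aortas moved these small values: without Dicer_KO replicate 1, U6 was at 0.40, snoRNA135 at -0.25 and snoRNA202 at -0.10, and without Dicer_KO replicate 2, U6 was at 0.085 and snoRNA135 at -0.069. snoRNA202 turned to 0.056 without Dicer_WT replicate 3, and snoRNA429 ranged from -0.15 without Dicer_WT replicate 2 to -0.022 without Dicer_WT replicate 1.

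**Figure D3:**
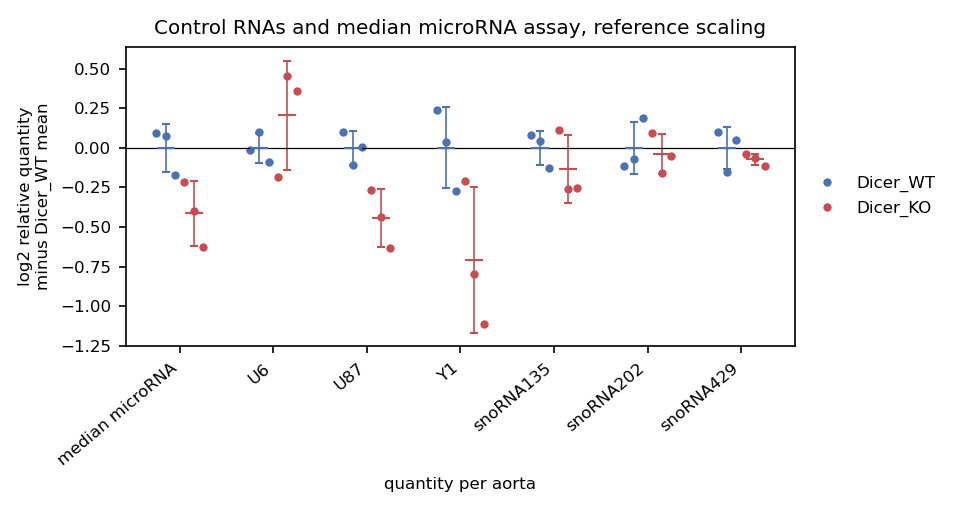
Level per aorta of the median microRNA assay and of 6 control RNAs on the reference scale, minus the Dicer_WT mean (vertical axis, log2), in Dicer_WT (blue) and Dicer_KO (red) aortas, with dashes and bars for the mean and SD of 3 aortas. U87 lay lower by 0.44 in Dicer_KO aortas and Y1 by 0.71, while U6 differed by 0.21.

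The profile of Dicer_KO replicate 1 correlated with the other Dicer_KO aortas at 0.52 and 0.53, against 0.79 between those 2. These profiles are differences from the same Dicer_WT mean, which by itself makes them correlate. The correlation without any change was not estimated. Leaving out Dicer_KO replicate 1 raised the count of called assays to 64, 55 lower and 9 higher, and the count was 11 without Dicer_KO replicate 2. It was 5 without Dicer_WT replicate 1, where miR-467d (adjusted p = 0.0560) and miR-431 (adjusted p = 0.178) no longer passed. miR-431 was lost also without Dicer_WT replicate 2 (adjusted p = 0.129), Dicer_WT replicate 3 (0.0626) or Dicer_KO replicate 2 (0.0836). The epithelial list lost its camera call without Dicer_WT replicate 3, Dicer_KO replicate 1 or Dicer_KO replicate 2 (adjusted p = 0.202, 0.0653 and 0.126). The liver and adipose list lost it without each aorta except Dicer_WT replicate 1 and Dicer_KO replicate 3 (adjusted p from 0.0682 to 0.141). The count of assays was 26 at a Ct cutoff of 32, 24 with a trended and robust variance, 22 over assays detected in all 6 aortas and 17 with silent wells left missing.

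In the authors' deposited table of fold changes, 515 of 517 assays equalled the ratio of the arithmetic means of the relative quantities (tolerance 0.001 on the log2 scale). The exceptions were let-7b, listed at 0.349 in the authors' deposited table against 0.668 from the quantities, and miR-195, listed at 0.133 against 0.796. The let-7b entry of the authors' deposited table equalled the ratio with Dicer_KO replicate 1 counted as 0 (0.349), and its miR-195 entry lay below the ratio from the quantities by a factor of 6. The authors' deposited table and the log2 fold changes of 377 assays correlated across assays at Pearson 0.785 and Spearman 0.957, with the same sign for 98.9%, though assays are not independent replicates. Of 106 folds over 2 or under 0.5 in the authors' deposited table, 60 involved a well at Ct 40 in at least 1 aorta.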

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

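Among the alternatives that kept all aortas, 269 values for the counts, medians, lists, detection and control RNAs and 920 values for named assays kept their direction and their side of the threshold, or stayed within the limits set for values without a test. Beside the former 269, 23 lost the threshold, 4 newly passed it, 32 turned direction and 29 moved. Of the named assays, 51 values passed the threshold where the reported value did not, 6 lost it and 40 changed sign. The calls of miR-501-3p, miR-504, miR-665 and miR-881* passed in all 19 settings that tested them. miR-761 passed in 18 of 19, miR-467d in 18 of 21 and miR-431 in 14 of 21. Among the settings that kept all aortas, miR-761 was lost at a cutoff of Ct 32 (-0.21, adjusted p 0.513), miR-467d after quantile normalization (-1.75, adjusted p 0.103) and with the replicate block (adjusted p 0.0582), and miR-431 relative to U6 alone (-2.43, adjusted p 0.0549), with no filter on detection (adjusted p 0.0577) and with wells at Ct 40 taken as measured (adjusted p 0.0526). Assays silent in the Dicer_KO aortas could not be tested where undetected wells were missing or detection in all aortas was required. The adjusted p ranged from 2.46e-05 to 0.946 for the Dlk1-Dio3 list, from 0.0145 to 0.946 for the myeloid list, from 0.00927 to 0.946 for the epithelial list and from 0.0162 to 0.946 for the liver and adipose list, over camera with either correlation and fry. Wells near the cutoff set the limit of these arrays: only a bound is known for an assay with no product in a group. With the replicate block in limma, 7 assays passed, 7 of them lower and 0 higher, and 6 of these were among the 7 called without the block. Same-numbered aortas deviated together by correlations of 0.18, -0.10 and 0.15 over 330 assays, so the numbers were not read as pairs. The block changed no call of a list.

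For the lists, the value is the median log2 fold change of the members, and the direction is that of camera, which compares the members with the other assays. The cause of these changes was not tested beyond what each setting removes. On non-normalized Ct, the median over all assays was -0.64 and the control RNA differences were -0.65 for U87, -0.34 for snoRNA135, -0.24 for snoRNA202 and -0.26 for snoRNA429, with Y1 at -0.91 and U6 at 0.0023. The myeloid list (-1.16, adjusted p 0.0288) passed the threshold. Liver and adipose (0.043, adjusted p 0.0926) no longer passed. The sign of 1 assay turned, for miR-92a (-0.040). After centring each aorta on its mean over assays detected in all aortas, 1 assay was called higher and the median over all assays was -0.13. Epithelial (0.24, adjusted p 0.0898) no longer passed. The lists miR-10 family (-0.10, adjusted p 0.599), miR-29 family (0.12, adjusted p 0.0898), lipid metabolism (-0.072, adjusted p 0.746) and passenger strand (-0.18, adjusted p 0.599) turned direction. The sign of 9 assays turned, for miR-195 (0.042), miR-142-5p (0.28), miR-142-3p (0.29), miR-133a (0.043), miR-1 (0.30), miR-126-3p (0.36), miR-467b (0.21), miR-183 (0.15) and miR-193b (0.27). Relative to U6 alone, the median over all assays was -0.61. The myeloid list (-1.10, adjusted p 0.0246) passed the threshold. The list miR-29 family (-0.41, adjusted p 0.884) turned direction. After quantile normalization, 2 assays were called higher and the median over all assays was -0.010. Epithelial (0.47, adjusted p 0.154) and liver and adipose (0.68, adjusted p 0.0673) no longer passed. The lists miR-29 family (0.12, adjusted p 0.551) and lipid metabolism (-0.013, adjusted p 0.899) turned direction. The sign of 9 assays turned, for miR-142-5p (0.088), miR-142-3p (0.28), miR-1 (0.29), miR-126-3p (0.53), let-7f (0.10), miR-467b (0.16), miR-467e (0.15), miR-183 (0.38) and miR-193b (0.41). At a detection cutoff of Ct 32, 26 assays passed the threshold, 24 were called lower and 2 were called higher. The list miR-29 family (-0.25, adjusted p 0.997) turned direction. At a cutoff of Ct 38, the medians of lists that no longer passed were epithelial (-0.13, adjusted p 0.0518) and liver and adipose (0.27, adjusted p 0.0518). With undetected wells left missing, 17 assays passed the threshold, 16 were called lower and 1 was called higher. Epithelial (-0.13, adjusted p 0.109) and liver and adipose (0.27, adjusted p 0.0669) no longer passed. The list miR-29 family (-0.25, adjusted p 0.978) turned direction. Over assays detected in all 6 aortas, 22 assays passed the threshold, 20 were called lower and 2 were called higher. Epithelial (-0.18, adjusted p 0.109) and liver and adipose (0.27, adjusted p 0.0669) no longer passed. The list miR-29 family (-0.25, adjusted p 0.978) turned direction. With no filter on detection, the median over all assays was -0.22. The myeloid list (-0.87, adjusted p 0.0436) passed the threshold. Epithelial (-0.13, adjusted p 0.425) and liver and adipose (0.27, adjusted p 0.386) no longer passed. Lymphoid (-0.26, adjusted p 0.99), endothelial (-0.23, adjusted p 0.99), neuronal (-0.21, adjusted p 0.99), miR-15 family (-0.32, adjusted p 0.99), miR-17-92 (-0.18, adjusted p 0.99) and passenger strand (-0.29, adjusted p 0.99) turned direction. With a trended and robust variance in limma, 24 assays passed the threshold, 22 were called lower and 2 were called higher. Under camera with an estimated correlation, the medians of lists that no longer passed were epithelial (-0.13, adjusted p 0.946), liver and adipose (0.27, adjusted p 0.946) and Dlk1-Dio3 (-0.82, adjusted p 0.946). In fry, whose direction is the members' own balance, the medians of lists that no longer passed were epithelial (-0.13, adjusted p 0.727), liver and adipose (0.27, adjusted p 0.542) and Dlk1-Dio3 (-0.82, adjusted p 0.16). Lymphoid (-0.26, adjusted p 0.298), endothelial (-0.23, adjusted p 0.298), striated muscle (-0.067, adjusted p 0.809), neuronal (-0.21, adjusted p 0.542), miR-15 family (-0.32, adjusted p 0.404), miR-17-92 (-0.24, adjusted p 0.477) and passenger strand (-0.37, adjusted p 0.233) turned direction.

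These alternatives were chosen after seeing the data. With wells at Ct 40 taken as measured, 11 assays passed the threshold and 11 were called lower. The myeloid list (-0.87, adjusted p 0.0445) passed the threshold. Epithelial (-0.13, adjusted p 0.4) and liver and adipose (0.27, adjusted p 0.368) no longer passed. Lymphoid (-0.26, adjusted p 0.972), endothelial (-0.23, adjusted p 0.972), neuronal (-0.43, adjusted p 0.972), miR-15 family (-0.32, adjusted p 0.972) and miR-17-92 (-0.18, adjusted p 0.972) turned direction. Relative to U87 and Y1, 2 assays were called higher and the median over all assays was 0.16. Epithelial (0.38, adjusted p 0.312) and liver and adipose (0.78, adjusted p 0.106) no longer passed. The lists miR-10 family (0.042, adjusted p 0.778), miR-29 family (0.26, adjusted p 0.118) and lipid metabolism (0.074, adjusted p 0.841) turned direction. The sign of 18 assays turned, for miR-195 (0.19), miR-132 (0.099), miR-142-5p (0.42), miR-142-3p (0.44), miR-27b (0.013), miR-24 (0.080), miR-145 (0.096), miR-133a (0.19), miR-1 (0.44), miR-218 (0.062), miR-126-3p (0.51), let-7f (0.093), let-7g (0.13), miR-467a (0.013), miR-467b (0.36), miR-467e (0.12), miR-183 (0.30) and miR-193b (0.42). Relative to the snoRNA assays, 12 assays passed the threshold and 2 were called higher. Liver and adipose (0.35, adjusted p 0.0716) no longer passed. The list miR-29 family (-0.17, adjusted p 0.708) turned direction. The sign of 3 assays turned, for miR-142-3p (0.008), miR-1 (0.015) and miR-126-3p (0.077).

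Leaving out each aorta in turn gave 5 to 64 assays past the threshold, 5 to 55 lower and 0 to 9 higher. The count was 64 without Dicer_KO replicate 1, 11 without Dicer_KO replicate 2 and 5 without Dicer_WT replicate 1. The list medians whose call or direction changed without 1 aorta ranged from -0.26 to 0.14 for epithelial, from 0.084 to 0.39 for liver and adipose, from -0.67 to -0.094 for miR-10 family, from -0.39 to -0.16 for miR-17-92, from -0.30 to -0.14 for miR-29 family, from -1.15 to -0.78 for myeloid, from -0.72 to 0.38 for neuronal, from -0.61 to -0.37 for smooth muscle and from -0.35 to 0.17 for striated muscle. The assays whose sign changed without 1 aorta ranged from -0.35 to 0.17 for miR-1, from -0.23 to 0.24 for miR-126-3p, from -0.24 to 0.030 for miR-142-3p, from -0.21 to 0.024 for miR-142-5p, from -0.66 to 0.25 for miR-183 and from -0.26 to 0.058 for miR-193b.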

Other observations

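The explanations and tests of these paragraphs were chosen after the results had been seen. Members of the miR-467 family, which share most of their sequence, differed in their values. miR-467d fell by 2.67 (limma adjusted p = 0.0083), whereas miR-467c was at -0.81 ± 0.230 (SE, n = 3 each, limma adjusted p = 0.101), miR-467a at -0.50, miR-467e at -0.39 and miR-467b at -0.15, none of which passed. Relative to U87 and Y1, miR-467a, miR-467e and miR-467b turned above 0, the latter pair also after quantile normalization and miR-467b after mean centring. Without 1 aorta, miR-467a ranged from -0.75 to -0.33, miR-467e from -0.60 to -0.21 and miR-467b from -0.24 to -0.084. The differences between members were not tested. The cluster of miR-183, miR-96 and miR-182, known from sensory cells and epithelia, had log2 fold changes of -0.21 ± 0.462, 2.49 ± 1.19 and 1.70 ± 0.327, a difference between cotranscribed members that was not tested; miR-183 turned above 0 with mean centring, quantile normalization and U87 and Y1. The lymphocyte microRNA miR-150 was at 0.53 ± 0.316 (limma adjusted p = 0.274) and the adipose-enriched miR-193b at -0.09 ± 0.238 (limma adjusted p = 0.767), which turned above 0 with mean centring, quantile normalization and U87 and Y1.

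Most assays lay lower in Dicer_KO aortas. The choice of reference could account for the shift, since the median became 0.16 relative to U87 and Y1, and which control RNAs were stable is open. An equal loss of RNA in every Dicer_KO reaction would move microRNAs and every control RNA alike. It would cancel on the authors' scale, which subtracts reference RNAs, so alone it cannot give the median of -0.42 there. For the median of -0.64 on non-normalized Ct such a loss stays open. The per-aorta microRNA median moved by 0.14 relative to U87 and Y1, 1.28 SD of the aortas with overlapping groups. U6 counts against an equal loss, at 0.0023 on non-normalized Ct. Relative to U6, however, the microRNA median moved by -0.62, 1.68 SD with overlapping groups, which excludes nothing. Loss of Dicer in myeloid cells alone would leave smooth muscle microRNAs in place, and their per-aorta median moved by -0.49 on the authors' scale and by 0.025 relative to U87 and Y1, so this cannot be told apart from the reference while the scale is open.

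Of the 7 assays detected in every Dicer_WT aorta and silent in all Dicer_KO aortas, 6 had a mean Dicer_WT Ct below 32, whereas miR-488 lay nearer the cutoff. Independent failure of single wells at an equal rate for all assays is argued against. The rate of single failed wells, 1.00% of Dicer_KO wells, gives 0.000351 assays with all 3 silent and 0.104 with 2 silent. Of 347 well-measured assays 6 and 9 were, 8 of the 9 in Dicer_KO replicates 2 and 3 together. A failure rate that rises with Ct was not tested. The mean Dicer_WT Ct was 30.1 for miR-881*, 30.5 for miR-665, 31.1 for miR-147 and 31.6 for miR-761, against 25.1 for miR-501-3p and 27.4 for miR-504. Loss of the whole miR-501 hairpin is argued against by miR-501-5p, at -3.38 (-1.65 without the silent Dicer_KO replicate 3, -4.33 without Dicer_KO replicate 1) and detected in 2 Dicer_KO aortas, where miR-501-3p was at or below -9.65, although miR-501-5p was itself called lower with undetected wells left missing (adjusted p = 0.0460). An array lot that differed between genotypes may account for the set and cannot be told apart from the genotype, as no lot is recorded, and 0 assays were silent in every Dicer_WT aorta alone. Loss of these microRNAs in lysozyme M-expressing cells was not tested and stays open too. In the same aortas the granulocyte and macrophage miR-223 was only 3.17-fold lower, against at least 802-fold for miR-501-3p. How completely such cells lost Dicer was not measured.

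On the authors' scale all 11 myeloid assays had a log2 fold change below 0, though relative to U87 and Y1 miR-132, miR-142-3p and miR-142-5p turned above it, and the difference of miR-142 from the other members was not tested. The general shift of all assays is argued against as the whole cause, since the myeloid median moved by -0.61 against the other assays (-2.74 SD, no overlap of the groups), although the list did not pass in camera (adjusted p = 0.0757). Fewer leukocytes of every kind would lower lymphoid microRNAs too, and the lymphoid median moved by 0.78 against the myeloid median (2.39 SD, no overlap), and the intervals of miR-142-3p (-0.63 to 0.48), miR-142-5p (-0.60 to 0.43) and miR-150 lay above the myeloid median of -0.93, which counts against it; but miR-142 was singled out by its values and the intervals of miR-181c and miR-31 reached below that median, so this is not excluded. Loss of Dicer in macrophages, with miR-142 kept up by lymphocytes, might give such values, and miR-150 at 0.53 with a 95% interval of -0.24 to 1.31 left that open (0.24 without Dicer_WT replicate 1). Both comparisons of medians have an exact permutation p of 0.1, the smallest possible.

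Of the 10 splits of the 6 aortas into 3 against 3, 1 gave as many as 7 calls, that of the genotypes itself, and the highest other count was 1. As many lists as the 3 of the genotypes were called by camera in 4 of the 10 splits, the genotypes included, with a highest other count of 3. Camera called at least 1 list in most of the other splits. Each of those splits mixes the genotypes unequally in its groups, so part of any genotype difference remains in it. Whether a list call at the preset correlation was particular to the genotypes therefore cannot be told from the splits. Such few splits cannot give a share under 0.05.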
